A study of Homo sapiens with 2 samples.

How the data were processed

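RNA was measured in 2 lines made from BxPC-3, a human pancreatic cancer cell line. One line re-expressed wild-type DPC4 (also called SMAD4, a transducer of TGF-beta signals) and the other carried an empty vector. Each line was represented by 1 2-colour Agilent array. Per the labels, RNA of control cells at 24 h was labelled with Cy5 and RNA of cells treated for 24 h with UA62001, a compound known here by its code name, was labelled with Cy3 on both arrays. No dye-swapped array and no replicate array was analysed here, so each value has no replicate check and no p-value or standard error across arrays is given. With 1 array per line, the number of arrays limits the precision.

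The authors deposited 1 log ratio of the channels per feature (a spot of the array) for 22153 features on each array. Extraction software, background correction and dye normalization are not given in the sources used here. The scale was taken as log10 from the deposited values themselves, which have 3 significant digits and exact zeros and whose identifiers run as feature numbers up to 22575. The lower and upper quartiles of the deposited log10 values were -0.0612 and 0.052 on the DPC4 array and -0.0512 and 0.0447 on the vector array, and the medians were 0.00506 and 0. A log2 scale would place the upper quartile only 3.67% and 3.15% above no change, and is kept as an alternative. The deposited ratios do not state their numerator. Centring is also not stated. No spot intensities were used, so dim and bright features could not be told apart and no background limit was applied.

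Deposited values were multiplied by the base-2 logarithm of 10 and used without further centring. The platform's annotation gave a symbol to 18060 features, of which 17 had several symbols and were not used, and 4093 features had none. Symbols were updated by gene identifier through a RefSeq gene table of the GRCh38.p14 assembly, which held 18031 of the named features. That table was used for names only, and no genome build of the array was given, so no coordinates are printed. Features of a gene were averaged, which gave 15509 genes, 13807 with 1 feature and 1702 with several. All measured columns were used.

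The comparisons, the gene lists, the threshold and the other settings to be tried were fixed before the data were examined. Genes with a ratio of 2-fold or more (an absolute log2 ratio of 1 or more) were counted on each array, on both arrays with the same sign, and for the difference, which is the DPC4 log2 ratio minus the vector log2 ratio. The overlap was set beside the number expected of independent lists. For 29 gene lists, with 10 to 49 measured members each and 793 of 881 fixed members measured, the median log2 ratio was placed among the medians of 10000 random lists of the same size drawn from all measured genes. Random lists could not be matched on intensity. A list is said to lie outside the random range when its median fell below the 2.5th or above the 97.5th percentile. Over 87 such comparisons, lists of randomly drawn genes would lie outside in about 5%. Genes of one list that vary together can lie outside more often. The 87 are also not separate, since the differences are formed from the values of both arrays. The percentile of a list describes these arrays and is not a test of the treatment.

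The lists were DNA replication and G1/S genes, mitosis and G2/M genes, histones, p53 targets, DNA repair and checkpoint genes, apoptosis genes, TGF-beta and SMAD genes, endoplasmic reticulum stress and ATF4 genes, heat shock genes, NRF2 oxidative stress genes, metallothioneins, xenobiotic metabolism genes, cholesterol and fatty acid synthesis genes, hypoxia and glycolysis genes, NF-kappaB and inflammatory genes, interferon-stimulated genes, immediate early genes, epithelial-mesenchymal transition genes, keratins, pancreatic duct and cancer markers, tubulins and actin cytoskeleton genes, MYC targets, cytosolic ribosomal proteins, proteasome subunits, oxidative phosphorylation subunits, common reference genes, and markers of acinar and islet cells, of fibroblasts and stellate cells, and of leukocytes and endothelium. Genes named in the text are the 12 furthest on each side on each array and for the difference, SMAD4, and up to 4 members per list with the largest absolute mean of the arrays. A gene whose features had opposite signs past 1.5-fold on one array (25 genes) or that was listed at exactly 0 on either array (282 genes) was not ranked. Other named genes are said to have been chosen after their values were seen.

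The other settings were centring each array on its median, other ways of joining features of a gene, scaling both arrays to one spread, thresholds of 1.5-fold and 3-fold, leaving out features at 0, counting features, Spearman's correlation, the mean of list members, a log2 reading of the values and the opposite sign. A further setting was chosen after seeing the data. Feature numbers were laid out in 105 lines of 215, the width at which neighbouring lines of the DPC4 array correlated most (r = 0.156). A feature was called disturbed when over 5% of the other named features in the surrounding window of 15 by 15 were past 2-fold on one side, with a limit of 10% as a second choice. The limit was also applied to DPC4 values shuffled over the named positions, in 100 shuffles. The layout is inferred from the values and was not given. The steps were tested on simulated data. Of 200 genes among 15509, those given a change of 1.5 and of 2 on the log2 scale were found past 2-fold on both arrays in 96% and 100%, and lists of 30 genes with no shift fell outside the random range in 6.5%. The noise for these rates was independent between genes and arrays, without disturbed parts. Its spread was 0.23, that of the centre of the vector array, against an SD over genes of 0.59 on the DPC4 array. These rates therefore need not hold for the measured arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.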

Results

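Gene expression was compared between control and UA62001-treated BxPC-3 pancreatic cancer cells at 24 h, on 1 array for the line that re-expressed DPC4 and 1 array for the empty-vector line. BxPC-3 was derived from a pancreatic adenocarcinoma, and DPC4 is a tumour suppressor that is often lost in this cancer. The pair of lines allows the question of whether the expression response to UA62001 differs with DPC4. Values are log2 ratios from the deposited log ratios, with the deposited sign. The labels place control RNA in the Cy5 channel and treated RNA in the Cy3 channel, and which channel is the numerator is not stated. The form of the values is that of the scanner software's ratio of Cy5 over Cy3, so a positive value likely means more signal in control cells and a negative value more signal in treated cells. Because this reading rests on the form of the values alone, genes are described by the side on which they lie. There was no replicate array, and no difference below was tested against replicate error.

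On the vector array, genes of DNA replication, mitosis and DNA repair lay on the positive side, and genes of the oxidative stress response and of the ATF4 amino acid response lay on the negative side. The replication and G1/S list had a median log2 ratio of 1.02 (2.03-fold) over 43 genes, with 41 genes positive and 22 of them past 2-fold. TYMS, which makes thymidylate for DNA synthesis, had 1.82, the replicative helicase subunits MCM6 and MCM3 had 1.69 and 1.39, and the polymerase clamp PCNA had 1.47. All 42 mitosis and G2/M genes were positive, with a median of 0.74 and 12 past 2-fold, among them TOP2A at 1.49, CENPF at 1.44, NEK2 at 1.30 and KIF20A at 1.26 ± 0.07 (SD over 10 features). DNA repair and checkpoint genes had a median of 0.67 over 27 genes, with EXO1 at 1.34, UNG at 1.23 and CHEK2 at 1.11.

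The NRF2 oxidative stress list had the median furthest to the negative side on the vector array, -0.46 over 22 genes, with 20 negative. Heme oxygenase HMOX1 had -1.90, the glutathione synthesis subunit GCLM -1.27, and the redox genes TXNRD1 and SRXN1 -1.14 and -1.13. The endoplasmic reticulum stress and ATF4 list had a median of -0.42 with 26 of 27 genes negative. Its ranked members with the largest absolute mean of the arrays were the ATF4 targets TRIB3, ASNS (asparagine synthetase), PSAT1 (serine synthesis) and SHMT2. On the vector array they had -2.37, -2.32, -1.05 and -0.79. Cholesterol and fatty acid synthesis genes had a median of -0.29 over 22 genes, with SQLE at -0.95 and MSMO1 at -0.94. Medians on the negative side were also found for MYC targets and ribosome biogenesis genes (-0.16), p53 targets (-0.15), proteasome subunits (-0.13) and immediate early genes (-0.12). The p53 list held genes on both sides, with the cell cycle inhibitor CDKN1A at -1.26 and GADD45A at -1.11 against DDB2 at 0.91. The immediate early list was also mixed, with EGR1 at 2.74 and FOS at 2.06 against DUSP5 at -1.30 and FOSL1 at -0.86, and the mean of its members was 0.028. Histones (median 0.23), oxidative phosphorylation subunits (0.28) and interferon-stimulated genes (0.21) completed the 6 lists above the random range, and 7 lists lay below it.

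In all, 496 of 15509 genes passed 2-fold on the vector array, 341 on the positive and 155 on the negative side. The 12 genes furthest to the negative side ranged from -1.77 to -2.63 and included G0S2 (-2.63), a lipolysis inhibitor, CLEC12A (-2.16), SALL1 (-1.97) and ESM1 (-1.93 ± 0.21, SD over 10 features). Of the 12 furthest to the positive side, among them VEGFC (3.30), IPP (3.21), KIF14 (3.09) and ARHGAP11A (3.08), 10 lay in parts of the array where over 5% of neighbouring features were past 2-fold on one side, and only EGR1 passed 2-fold on the same side on the other array. Without features in such parts of either array, 254 of 10576 genes passed 2-fold, and the p53 median was -0.39.

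On the DPC4 array the same proliferation lists lay on the positive side and the same stress lists on the negative side. The replication and G1/S median was 0.68 (1.61-fold), with 38 of 43 genes positive and 6 past 2-fold on that side, including TYMS at 1.49, MCM6 at 1.27, PCNA at 1.14 and MCM3 at 1.06. The mitosis and G2/M median was 0.55, with 40 of 42 positive, and the DNA repair median was 0.50, with 21 of 27 positive. The NRF2 median was -0.41, with HMOX1 at -1.79 and GCLM at -1.21, and the ATF4 list median was -0.26, with TRIB3 at -2.11 and ASNS at -2.10. The p53 median was -0.41 with 19 of 26 negative, including CDKN1A at -1.32 and GADD45A at -1.18, while DDB2 had 0.84. Gene by gene, the median p53 difference (DPC4 minus vector) was -0.01, inside the random range, with 12 genes higher and 14 lower on the DPC4 array.

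Other lists outside the random range on the DPC4 array were histones (0.26), interferon-stimulated genes (0.30) and oxidative phosphorylation subunits (0.20) on the positive side. On the negative side were cholesterol and fatty acid synthesis genes (-0.25), proteasome subunits (-0.24), tubulins and actin cytoskeleton genes (-0.21), MYC targets (-0.20), epithelial-mesenchymal transition genes (-0.18), immediate early genes (-0.15), NF-kappaB and inflammatory genes (-0.14), apoptosis genes (-0.11), hypoxia and glycolysis genes (-0.10) and cytosolic ribosomal proteins (-0.07). The apoptosis, hypoxia and ribosomal protein medians lay near the edge of the range, at percentiles 2.43, 2.25 and 2.1. With the mean of members in place of the median, all lists of this negative side lay inside the range, while the other 9 lists outside it on this array stayed outside. Most of the means lay no nearer to 0 than the medians. They were -0.28 for cholesterol synthesis, -0.27 for proteasome, -0.18 for cytoskeleton, -0.23 for MYC target and -0.19 for epithelial-mesenchymal genes. Immediate early genes had -0.05, inflammatory -0.28, apoptosis -0.26, hypoxia -0.10 and ribosomal protein genes -0.08. Random means, however, spread more widely and reached further below 0 than above it. For proteasome subunits they ran from -0.32 to 0.13, against -0.10 to 0.12 for medians. For hypoxia and ribosomal protein genes they ran from -0.30 to 0.11 and from -0.25 to 0.08. The distance of a mean from 0 is therefore not its shift from random lists. On the vector array the cytoskeleton (0.00), epithelial-mesenchymal (-0.06), inflammatory (-0.03), apoptosis (-0.01), hypoxia (0.00) and ribosomal protein (-0.04) medians lay inside the random range. The median differences (DPC4 minus vector) of epithelial-mesenchymal (-0.0009), inflammatory (0.007), hypoxia (-0.01) and apoptosis genes (-0.04) also lay inside their random range. With the mean of members, inflammatory genes lay below the range on the vector array, at -0.19 against a lower limit of -0.10. Within the inflammatory list the interleukins IL1B and IL1A had -1.62 and -1.50 and the plasminogen activator system genes PLAU and PLAUR -1.31 and -1.19, with similar values of -1.64, -1.42, -1.48 and -1.25 on the vector array.

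A total of 1023 genes passed 2-fold on the DPC4 array, 238 on the positive and 785 on the negative side. The 12 furthest negative genes, from F2RL2 (-4.58) and LRRC43 (-4.32) to CKMT2 (-3.92), each had 1 feature, and 11 lay in disturbed parts of the array, where 14.0% of named features were at or below -1 against 1.43% elsewhere. Only 4 of the 12 passed 2-fold on the negative side of the vector array too. The 12 furthest positive genes included ALDH1A1 (2.69), a retinaldehyde dehydrogenase, the linker histone H1-3 (2.53), EGR1 (2.47), the chemokine CXCL14 (2.22), the alcohol dehydrogenase ADH7 (2.19) and BMP7 (2.18), and 9 of them also passed 2-fold on the vector array. Without features in disturbed parts, 323 of 10576 genes passed 2-fold, 182 positive and 141 negative, and the medians of apoptosis and of inflammatory genes were 0.027 and 0.026. That of the ATF4 list was then -0.15 and that of MYC targets -0.11, both still below the random range. Of the genes named above, TYMS, PCNA, TOP2A, ASNS, PSAT1, GCLM, TXNRD1, SQLE, MSMO1, FOS, DUSP5, PLAU, PLAUR, ALDH1A1 and BMP7 had their feature in a disturbed part of the DPC4 array, and TRIB3, SRXN1, UNG and MSMO1 in one of the vector array.

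**Figure D1:**
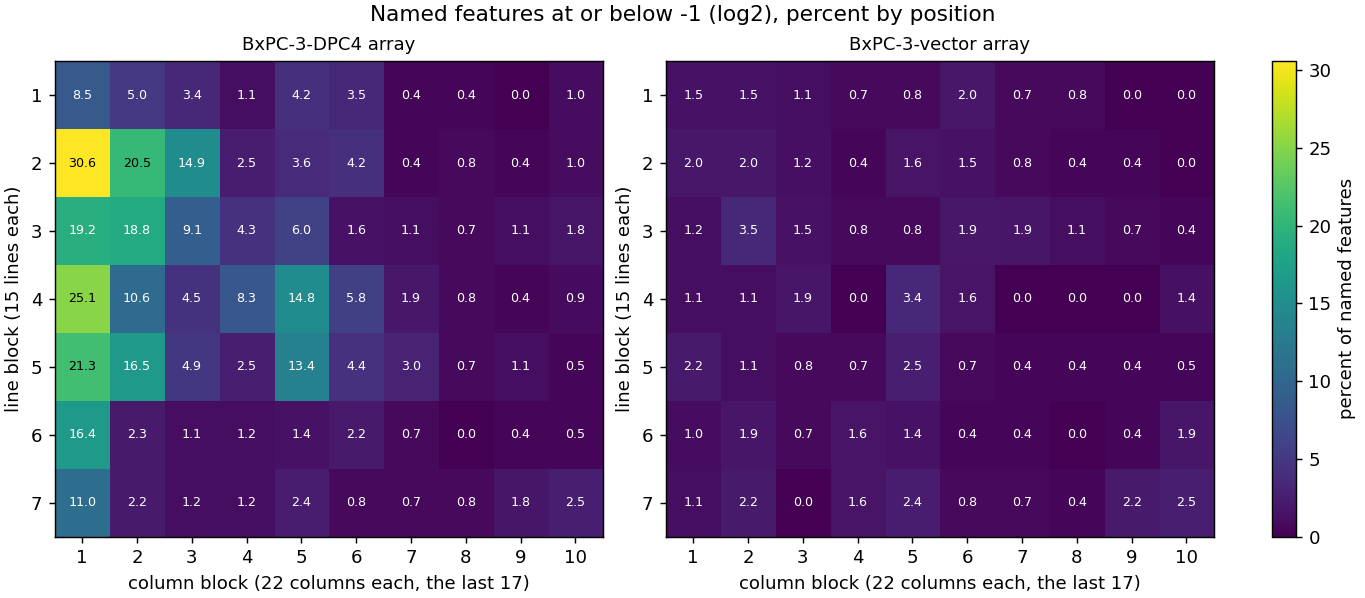
Percent of named features with a log2 ratio at or below -1 in blocks of the inferred layout, columns on the horizontal and lines on the vertical axis, for the DPC4 array (left) and the vector array (right). On the DPC4 array the share is 18.8% in the first column block and 0.598% in the eighth.

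**Figure D2:**
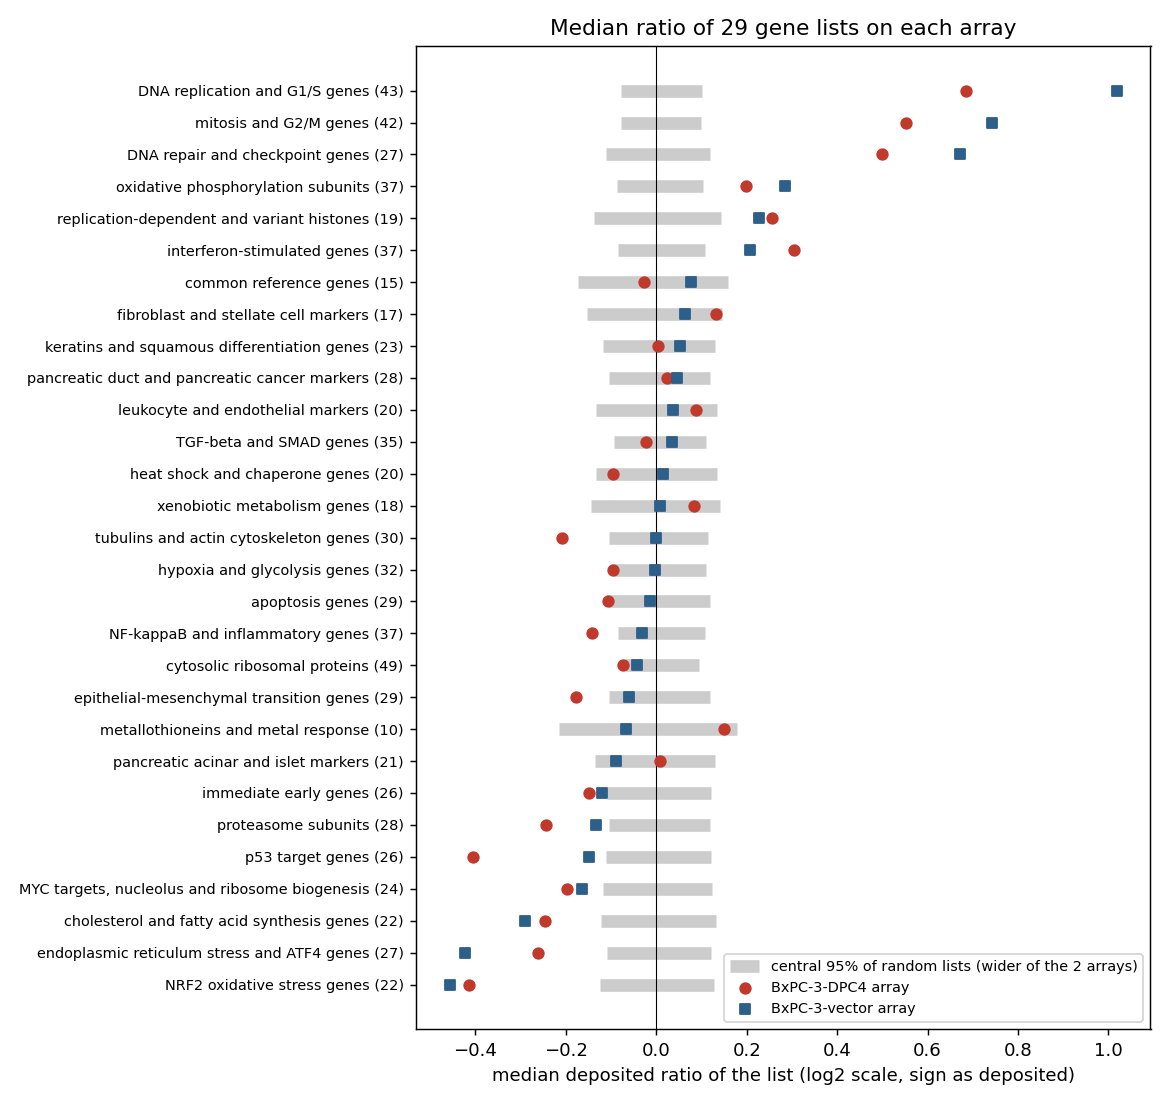
Median log2 ratio (horizontal axis, sign as deposited) of each of 29 gene lists, with the number of measured members, on the DPC4 array (circles) and the vector array (squares); grey bars span the central 95% of random lists. Replication genes lie furthest to the positive side, at 0.68 and 1.02, and NRF2 genes furthest to the negative side, at -0.41 and -0.46.

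Many of the same genes lay past 2-fold on both arrays. Positive on both were EGR1 (2.47 on the DPC4 and 2.74 on the vector array), ALDH1A1 (2.69 and 2.49), ADH7 (2.19 and 2.62), CXCL14 (2.22 and 2.22), H1-3 (2.53 and 1.92) and KRT13 (1.52 and 1.64), a keratin of stratified epithelia. Negative on both were G0S2 (-2.56 and -2.63), TRIB3, ASNS, HMOX1, IL1B, the laminin subunit LAMB3 (-1.18 and -1.44) and the transferrin receptor TFRC (-1.18 and -1.25). The positive side held 133 shared genes, where independent lists would share 5.23, and the negative side held 96, where they would share 7.85. A further 25 genes passed 2-fold with opposite signs. Without disturbed features the shared counts were 100 and 42 and no gene had opposite signs.

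Across all 15509 genes the arrays correlated with Pearson's r = 0.452 and Spearman's rho = 0.694, and across the 10576 genes without disturbed features with 0.746 and 0.813. Genes are not independent replicates, and both arrays had the same dye orientation, so a bias of a probe towards one dye would add to the overlap and to the correlation.

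**Figure D3:**
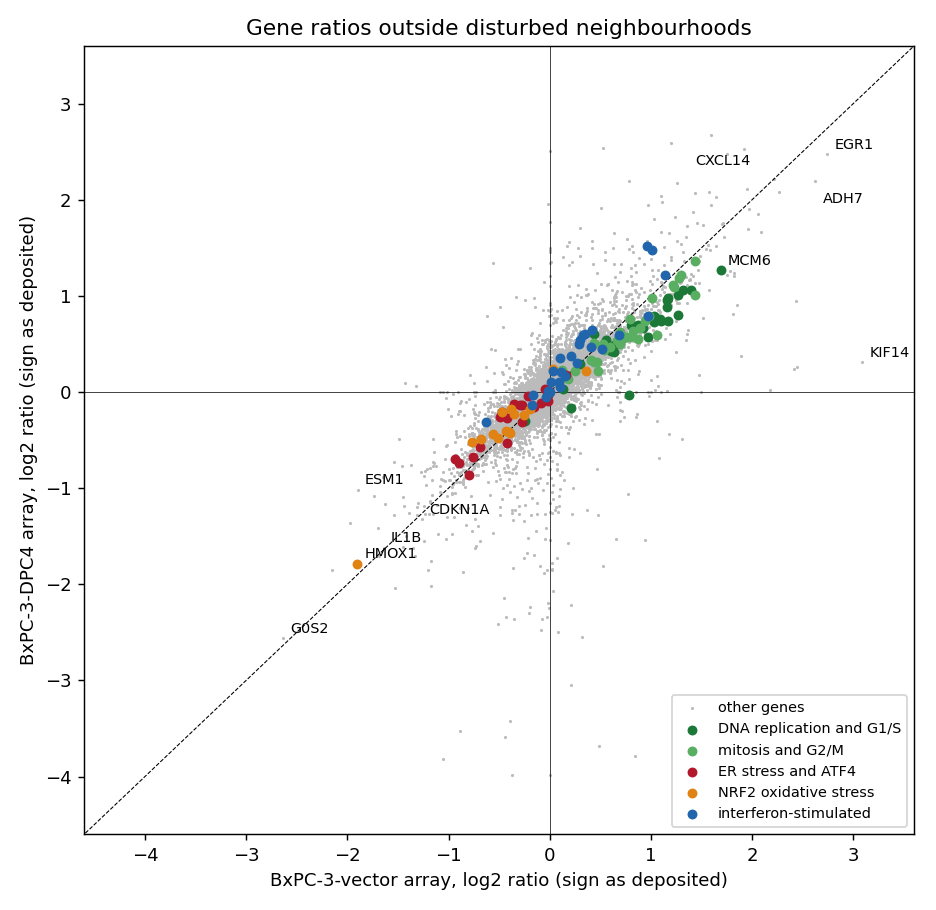
Log2 ratio of each gene on the vector array (horizontal axis) and on the DPC4 array (vertical axis), sign as deposited, for 10576 genes without features in disturbed parts of either array; colours mark 5 gene lists and the dashed line marks equal values. Replication and mitosis genes lie on the positive side of both arrays, mostly under the line, with MCM6 at 1.69 and 1.27.

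Between the lines, the genes of DNA replication had lower positive values on the DPC4 array than on the vector array. The median difference was -0.25 (1.19-fold) over 43 genes, and 41 of the 43 were lower on the DPC4 array, among them MCM6 (-0.42), MCM3 (-0.33), PCNA (-0.33) and TYMS (-0.33). DNA repair genes had a median difference of -0.17 with 23 of 27 lower, and mitosis genes -0.13 with 39 of 42 lower. On the other side, the median difference was 0.21 for metallothioneins and metal response genes, 0.09 for leukocyte and endothelial markers and 0.08 for ATF4 and endoplasmic reticulum stress genes, the last with 19 of 27 genes higher on the DPC4 array. The near-identical metallothionein genes, such as MT1E (0.21 and -0.06) and MT1X (0.16 and -0.06), can share signal and are not separate measurements.

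Smaller negative differences outside the random range were found for tubulins and actin cytoskeleton genes (-0.11), keratins (-0.08), heat shock genes (-0.08), oxidative phosphorylation subunits (-0.08), cytosolic ribosomal proteins (-0.07) and proteasome subunits (-0.06). With the mean of members, the differences of these lists and of mitosis and DNA repair genes lay inside the wider random range of means. They were -0.14 for cytoskeleton, -0.11 for keratin, -0.10 for heat shock and -0.10 for oxidative phosphorylation genes. Ribosomal protein genes had -0.06, proteasome -0.10, mitosis -0.15 and DNA repair genes -0.23. The ranges for mitosis and DNA repair genes were -0.27 to 0.05 and -0.32 to 0.07. Those of the other lists also reached further below 0 than above it. For ribosomal protein genes the range was -0.25 to 0.04 and for heat shock genes -0.37 to 0.09. Negative means of this size are therefore usual among random lists. The leukocyte mean turned negative, and those of replication, metallothionein and ATF4 genes stayed outside, joined by interferon-stimulated genes. Without disturbed features the replication median difference was -0.24, that of cytoskeleton genes -0.07, and the ATF4 and leukocyte medians, 0.09 and 0.10, lay inside the random range, while those of NRF2 genes (0.11) and common reference genes (-0.06) lay outside it.

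Several of these genes are measured by 10 features on each array, which gives the spread within an array but not between cultures. The following genes other than EXO1, KIF20A and ESM1 were chosen after their values were seen. In features outside disturbed parts, the DNA primase subunit PRIM1 had 0.89 ± 0.09 on the DPC4 and 1.16 ± 0.07 on the vector array, WDHD1, a replisome factor, 0.96 ± 0.01 and 1.17 ± 0.01, EXO1 1.17 ± 0.04 and 1.39 ± 0.09, and the ubiquitin-conjugating enzyme UBE2C 0.57 ± 0.02 and 0.75 ± 0.06 (SD over features). These values rest on 5 undisturbed features for PRIM1, 5 for WDHD1, 7 for EXO1 and 7 for UBE2C. Counting disturbed features too, each of these genes was lower on the DPC4 array in 10 of 10 features. For the mitosis genes KIF20A, at 1.18 ± 0.08 and 1.28 ± 0.06, CCNA2, at 0.45 ± 0.04 and 0.52 ± 0.06, and CENPE, at 0.50 ± 0.06 and 0.53 ± 0.04, the difference was about the size of the spread or smaller. The interferon-stimulated gene IFI27 was higher on the DPC4 array in 10 of 10 features, at 0.59 ± 0.01 and 0.33 ± 0.01. ESM1 (endocan), on the negative side of both arrays, had -1.01 ± 0.25 on the DPC4 and -1.90 ± 0.15 on the vector array in undisturbed features, while all features together gave -1.52 ± 0.87 and -1.93 ± 0.21.

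**Figure D4:**
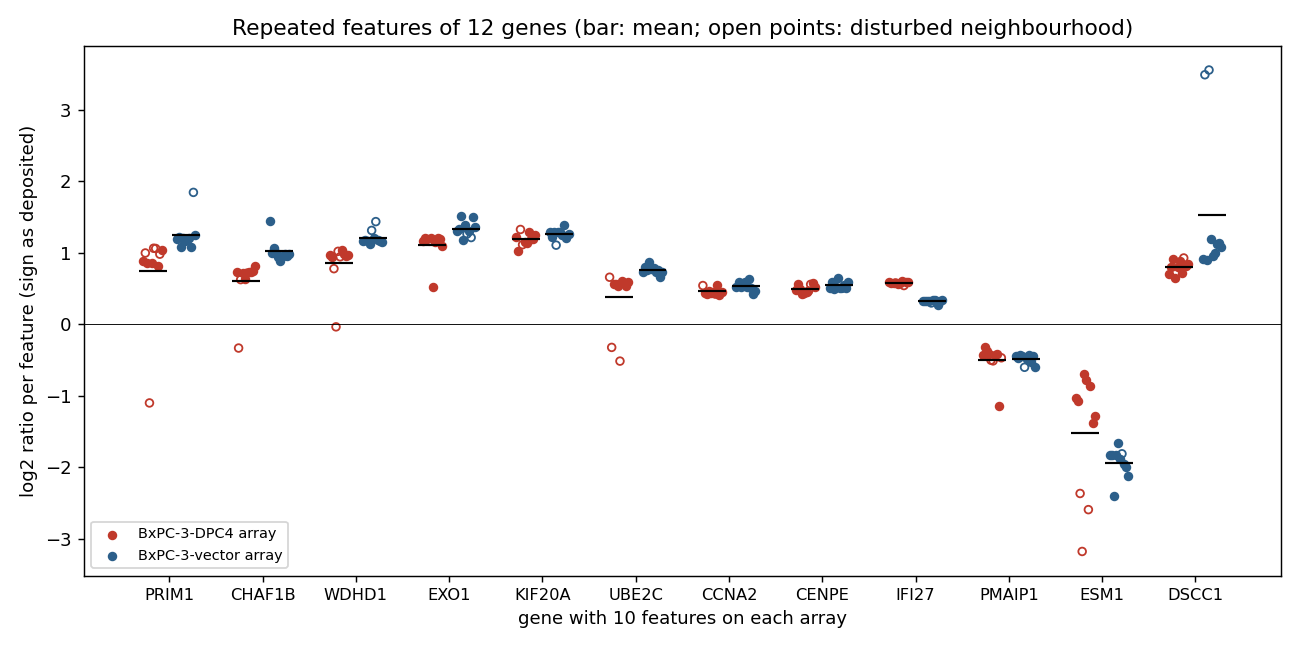
Log2 ratio (vertical axis, sign as deposited) of each of 10 features of 12 genes on the DPC4 array (left of each pair) and the vector array (right); bars are means over all 10 features, open points lie in disturbed parts of an array, and the genes other than EXO1, KIF20A and ESM1 were chosen after their values were seen. PRIM1, WDHD1, EXO1 and UBE2C are lower on the DPC4 array in 10 of 10 features and IFI27 is higher in 10 of 10.

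In all, 809 genes differed 2-fold or more between the arrays, 748 with the lower value on the DPC4 array and 61 with the higher. The 12 furthest negative differences, led by CST7 (-6.03), GPSM2 (-5.16) and VEPH1 (-4.95), each rested on 1 feature, of which 9 were disturbed on the DPC4 array and 3 on the vector array, and REXO5 (-4.63) was disturbed on neither. Of the 12 furthest positive differences, OAS3 (2.75), BEST1 (2.01), RSPH10B (1.97) and TXNDC2 (1.90) led, and the OAS3 feature was disturbed on the vector array. Without disturbed features 131 of 10576 genes differed 2-fold, 88 lower and 43 higher on the DPC4 array.

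The TGF-beta and SMAD list, which holds the genes closest to DPC4 itself, lay inside the random range on both arrays, with medians of -0.02 and 0.04 over 35 genes. CDKN2B, a cell cycle inhibitor and TGF-beta target, had -0.98 on the DPC4 and -1.08 on the vector array, SPHK1 -0.91 and -1.13, and LTBP1 0.70 and 0.86. ID3 had -2.99 and -0.01, and the features of ID3, SPHK1 and SMAD4 were disturbed on the DPC4 array. SMAD4 had -0.18 and -0.14 from 1 feature, a ratio of treated and control cells within each line that does not measure its re-expression. The median difference of the list was 0.00, and -0.10, below the random range, without disturbed features.

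Other lists lay inside the random range on both arrays, though without disturbed features the heat shock median on the DPC4 array, -0.12, lay below it. Medians on the DPC4 and the vector array were -0.10 and 0.02 for heat shock genes, 0.08 and 0.01 for xenobiotic metabolism genes, 0.00 and 0.05 for keratins, 0.02 and 0.05 for pancreatic duct and cancer markers, -0.03 and 0.08 for common reference genes, and 0.15 and -0.07 for metallothioneins. With the mean of members, xenobiotic metabolism genes (0.27) and keratins (0.20) lay above the random range on the vector array. Markers of other cell types had medians of 0.01 and -0.09 for acinar and islet cells, 0.13 and 0.06 for fibroblasts and stellate cells, and 0.09 and 0.04 for leukocytes and endothelium. Such a ratio compares treated and control cells within each line, so these medians cannot show whether other cell types were present. Single members of these lists lay far from 0 on the DPC4 array in disturbed parts of it, such as the pancreatic lipase PNLIP (-3.39), FAP (-2.80) and CD14 (-2.28), against -0.22, -0.16 and -0.10 on the vector array.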

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

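Every test in this part was chosen after the result it bears on was seen, and tests that left a question undecided are given beside those added afterwards.

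Of the 12 genes with the furthest negative difference, 8 lay past 2-fold on opposite sides of the arrays, with differences (DPC4 minus vector, log2) of -6.03 for CST7, -5.16 for GPSM2, -4.95 for VEPH1, -4.91 for OR3A1, -4.78 for C1orf105, -4.77 for ANKRD53, -4.57 for KLK12 and -4.29 for TEX14. Each value rests on 1 feature per array, which lay in a disturbed neighbourhood of the DPC4 array (VEPH1, OR3A1, C1orf105, ANKRD53 and KLK12), of the vector array (GPSM2 and TEX14) or of both (CST7), and 0 genes lay past 2-fold on opposite sides in undisturbed features. They are not read as a difference between the lines, which was not tested. Features without a gene symbol, which no comparison used, held 295 that were past 2-fold on the negative side of both arrays. Of these, 241 were at or below -3 on both, with medians of -4.12 and -4.02, most often spaced 7 features apart, and no named feature reached that level on both. The sources used here do not say what these features are, and they are not read as transcripts.

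The DPC4 array had many negative values past 2-fold, such as those of LHX4 and ID3, that the vector array did not share. They lay in parts of the array, with a share 31.5 times higher in the highest than in the lowest of 10 column blocks, and the share outside disturbed neighbourhoods was 27.2% of the share over all features, against 87.7% to 111% in 100 shuffles of the positions, which argues against a response of the DPC4 line as the cause of most of them if responding genes are scattered over the array. Features of one accession inside disturbed neighbourhoods were lower than those outside by too little to decide, with a median of -0.032 log2 over 76 accessions. Added after that, the median SD over features of one accession was 4.77 times larger over all features than over undisturbed ones, and features at exactly 0 on the vector array, taken as dim, were past 2-fold negative 2.06 times as often as others in disturbed neighbourhoods, on only 99 such features. A disturbed surface with uneven background is therefore a candidate explanation, and a response of single genes such as RTN1 outside these parts stays open.

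Replication genes such as MCM6 and PRIM1 lay further from 0 on the vector array, and without disturbed features the median difference was still -0.24, which argues against the disturbed surface. A narrower scale of the DPC4 array stays open. In undisturbed features, 60% (6 of 10) of the other lists outside the random range on both arrays were nearer to 0 on the DPC4 array. With all features, only the ATF4, NRF2, cholesterol synthesis and oxidative phosphorylation lists among them were nearer to 0 there. Compared after the lists, the spread over genes was 1.05 times that of the vector array (bootstrap 95% interval 1.02 to 1.08), but noise of single features widens it. The slope of the DPC4 on the vector ratios was 0.82, which noise lowers. The SD over means of 89 repeated accessions was 0.80 times that of the vector array, and also 0.80 times over the 81 outside the proliferation lists. Those 81 still held genes such as the replisome factor WDHD1, lower on the DPC4 array in 10 of 10 features. This SD ratio therefore partly restates the pattern in question and cannot decide. An offset between arrays for abundant transcripts stays open, since the ribosomal protein difference was 28.3% of that of the replication genes. The re-expressed DPC4 gene may also account for it and cannot be told apart from a difference between single cultures or hybridisations with 1 array per line.

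Gene groups such as replication and ATF4 targets lay on one side on both arrays. A bias of single probes towards one dye, unrelated to gene function, would leave list medians inside the random range, and the lower of the replication medians was 0.68. A bias that follows transcript abundance up to the most abundant would carry the ribosomal proteins along. Their medians lay on the other side of 0, at -0.07 on the DPC4 and -0.04 on the vector array, where the ratio to the replication median was -0.0417. Dye normalization is not given and no intensities were used, so a bias at other signal levels was not tested. The UA62001 treatment may account for the groups, as a hypothesis, and with 0 arrays of swapped dyes it cannot be told apart from a dye bias that happens to follow gene groups.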

How the results depend on the processing

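The alternatives that leave out disturbed features were chosen after seeing the data, and the others before. Centring, joining features of a gene in other ways, one spread for both arrays and leaving out features at 0 kept each count within 1.5 times the reported one. Counts are given for the DPC4 array, the vector array, the difference and both arrays with one sign. They were 2153, 1565, 1389 and 886 at 1.5-fold and 510, 116, 492 and 31 at 3-fold, since the threshold itself moved. Read as log2, the deposited values gave 77, 0, 63 and 0. Without disturbed features by the 5% limit they were 323, 254, 131 and 142, partly because fewer genes were counted, and the correlation was 0.746. By the 10% limit the DPC4 count was 485, the difference 272 and the correlation 0.652. Spearman's correlation was 0.694. With the mean of members in place of the median, 9 lists on the DPC4 array and 4 for the difference lay outside the random range, against 19 and 12. For these 2 results random means spread more widely than random medians and reached further below 0 than above it. The vector array went the other way, with 15 lists outside by the mean against 13. There xenobiotic metabolism, inflammatory and keratin genes were gained and immediate early genes were lost. The sign of a list outside the range turned for apoptosis genes on the DPC4 array (0.027 by both limits), inflammatory genes there (0.026 by the 5% limit), immediate early genes on the vector array (mean 0.028) and the leukocyte and endothelial difference (mean -0.045), and the cause was not tested. Of 609 list results over 7 settings, 1 of them the mean, 521 kept their sign and side of the range, 36 turned sign inside it, 27 moved inside it and 20 moved outside it. Turning the sign exchanges the sides of all values. Signal over background was not used, so dim features limit single genes by an unknown amount. No paired analysis was possible because each line has 1 array.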

Other observations

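Among genes outside the lists, a few more lay on one side on both arrays in undisturbed features, named here after their values were seen. On the positive side were the linker histone H1-5 (2.08 on the DPC4 and 2.27 on the vector array), the testis chaperone CLGN (2.12 and 1.95), the elongation factor TCEA3 (1.85 and 2.06), the retinal transporter ABCA4 (1.69 and 1.96) and the sphingolipid synthesis subunit SPTSSB (1.66 and 2.09). On the negative side were the nuclear receptor RORB (-2.04 and -1.52), the protease ADAMTS3 (-1.71 and -1.68), the transcription factor ETV1 (-2.02 and -1.17) and the cytokine subunit IL23A (-1.61 and -1.45).

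Further genes with 10 features, also chosen after their values were seen, went both ways. ATAD2, KIFC1 and RAD54B were lower on the DPC4 array in 10 of 10 features, disturbed ones included. Their undisturbed differences were -0.24 ± 0.09, -0.24 ± 0.08 and -0.16 ± 0.04 (SD over 9, 6 and 9 features). Some other genes of replication, mitosis or repair differed by about their spread or less. The differences were -0.02 ± 0.08 for DBF4, -0.12 ± 0.24 for RAD50 and 0.04 ± 0.13 for PARPBP (3 undisturbed features). CENPQ, CHAF1B and DSCC1 differed by -0.11 ± 0.07, -0.31 ± 0.19 and -0.21 ± 0.14. Counting disturbed features too, these 3 were lower on the DPC4 array in 9, 10 and 9 of 10 features. The repair helicase WRN was higher in 9 of 10 features, by 0.10 ± 0.04, and the transcription factor MYBL1 was higher in 10 of 10 features, by 0.09 ± 0.08. FOXA1 and HMGN5 differed by 0.00 ± 0.08 and 0.00 ± 0.05, with ratios of 0.53 and 0.75 on the DPC4 array. Of 89 accessions with 10 to 12 features, 25 had an undisturbed difference larger than 2 times its SD over features. Of these, 11 were lower on the DPC4 array and 14 higher. Counting disturbed features too, every feature was lower in 14 accessions and higher in 6. Disturbed parts of the DPC4 array held more negative values, so that last count can lean towards lower.

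Hypotheses on related gene groups were examined on both arrays. The tests of mitochondrial ribosomal protein and synthetase genes were set before their values were seen, and that of centromere protein genes was chosen after part of its values had been seen, since the mitosis list holds 3 of its members. Cytosolic aminoacyl-tRNA synthetase genes, which share regulation by ATF4 with ASNS, had medians of -0.29 and -0.30 over 18 genes, below the random range on both arrays, consistent with a shift shared by the amino acid response genes. Without disturbed features they were -0.18 and -0.21 over 10 genes, still below it. Centromere protein genes had medians of 0.38 and 0.54 over 16 genes, above the random range on both arrays. The mitochondrial ribosomal proteins did not share the positive side of the oxidative phosphorylation subunits, with medians of -0.028 and 0.05 over 75 genes, inside the random range on both arrays. Their median difference (DPC4 minus vector) was -0.07, below the random range, with 63 genes lower on the DPC4 array. That of centromere protein genes, -0.18, also lay below it, and that of synthetase genes, -0.006, lay inside.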
